A study of Mus musculus with 8 samples.

How the data were processed

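RNA was measured in 8 libraries of leukaemia cells from the spleens of Eµ-TCL1 mice, a transgenic model of chronic lymphocytic leukaemia in which B cells carry the TCL1 oncogene. Per the labels' protocols, CD5 and CD19 double-positive B cells were sorted by flow cytometry and libraries were made with an Illumina TruSeq kit. The series title names Zap70 expression, and the series design text gives 4 biological replicates for each of 2 conditions, wild type and knock-in. Libraries were grouped by their titles into WT and KI, 4 in each, and are named here by group and replicate number. The labels do not state where the knock-in lies, what sequence it carries, which animal gave which sample or whether cells were transplanted.

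The deposited file holds 1 value per Ensembl gene and library on a log2 scale, named by the authors as rlog values, the regularized logarithm of DESeq2. Per the submitters' processing notes, the tools were Salmon 1.1.0 and DESeq2 1.28.1 and the builds GRCm38 and mm10, with no role or order given. The annotation release, the treatment of strand, the trimming and any filter on genes are not given in the sources used here. The rlog transform pulls differences of genes with few reads towards 0, so the fold changes below are on that shrunken log2 scale and understate changes of low genes. No counts were part of the data used here, so the depth of each library is unknown and no counting interval or detection floor is given. Precision therefore rests on the spread between the 4 libraries of a group.

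The file lists 41444 genes, of which 16101 stood at exactly 0 in all 8 libraries. Values ranged from -2.27 to 21.6. Symbols were found for 41157 genes (99.3%), and coordinates were taken from the GENCODE mouse annotation M21 on GRCm38. Genes with a mean of at least 3 over the 8 libraries and some variation between them were tested, 12610 in all, 12568 of them with a symbol. No count test was used, since the values are not counts. Differences, KI minus WT, were tested with limma 3.58.1 in R 4.3.3 (linear model without covariates, eBayes with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Intervals are 95% intervals from limma's moderated standard errors. Zap70 was tested by an exact two-sided permutation test over the 70 arrangements of 8 libraries into 4 and 4, for which the smallest possible p is 0.0286.

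Of 42 gene lists fixed before the data were examined, 39 had at least 5 tested members and were tested with limma's camera at a preset correlation between genes of 0.01, two-sided, with adjustment over the lists. Of the 863 symbols in the lists that are not immunoglobulin or T cell receptor segments, 858 were in the file. Camera with an estimated correlation, limma's fry and an exact permutation test of each list's mean per library stand beside it. Principal components were computed from the 1000 most variable tested genes.

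The rule for named genes was also fixed before the data were examined. It takes Zap70 and its paralog Syk, then up to 12 genes per direction that passed the threshold without overlap between the groups, ranked by size of change. Where fewer than 5 passed in a direction, the genes with the smallest p complete it to 5 and are said not to pass. Immunoglobulin and T cell receptor segments, unnamed gene models and pseudogenes are left out of that ranking. The rule then takes up to 4 members with the smallest p of each list described, and Xist and Ddx3y. Genes outside the rule are said to be chosen after their values were seen.

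The fit and the list test were checked on simulated values for the comparison of KI with WT, with 200 changed genes among 12610 in each of 5 runs. It called 26.0%, 72.0%, 80.8% and 90.4% of planted log2 changes of 1, 2, 3 and 4, and 5.48% of its calls were false. No run had fewer than 200 changed genes, while the real comparison called 2, so these rates need not hold for it. The mitosis genes had an estimated correlation of 0.82, and calls of lists so correlated are not judged from these runs. Alternatives were other filters on the mean, other scalings, other variance models, library weights, a replicate block, a sex score from Xist and Y-linked genes as a covariate, each library left out in turn, another threshold, a minimum change, and a fit without antigen receptor segments. A fit with the level of Ighv12-3 as a covariate and a fit without WT 1 and KI 3 were chosen after seeing the data.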

Results

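The data were gene expression profiles of sorted CD5 and CD19 double-positive B cells from the spleens of leukaemic Eµ-TCL1 mice, 4 libraries labelled WT and 4 labelled KI, for knock-in. The title places Zap70 at the centre of the comparison. Zap70 is a tyrosine kinase that acts downstream of the T cell receptor and is also found in part of human chronic lymphocytic leukaemias. The 2 groups were compared on deposited rlog values, which are on a log2 scale, and each value below is a group mean ± SD over 4 libraries unless a library is named. Depth is unknown, so a low value cannot be told from absence. The design text calls the samples biological replicates, but no label ties a library to an animal.

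Zap70 (Ensembl ENSMUSG00000026117, chromosome 1, 36761798 to 36782818, GRCm38) averaged 6.52 ± 0.85 in KI and 5.06 ± 1.04 in WT (SD, n = 4 each). The difference was 1.46 on the log2 scale, with a 95% interval from 0.08 to 2.84. The groups overlapped: WT 1 stood at 6.47, above KI 1 at 5.56 and KI 2 at 6.30, while KI 3 held the highest value of the 8 libraries at 7.62. WT 4 held the lowest at 3.98. The exact permutation test gave p = 0.0857, and limma gave an unadjusted p of 0.0404 and an adjusted p of 0.999, so the difference passed neither the exact test nor the adjustment over all genes. Syk, the kinase that takes the place of Zap70 downstream of the B cell receptor, stood far above it, at 15.22 ± 0.24 in KI and 15.49 ± 0.23 in WT (exact permutation p = 0.200). These values do not separate the libraries labelled WT from those labelled KI, and every direction below rests on the labels. The level measured is that of the mouse Zap70 gene, and whether it covers the inserted sequence is not given in the sources used here.

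**Figure D1:**
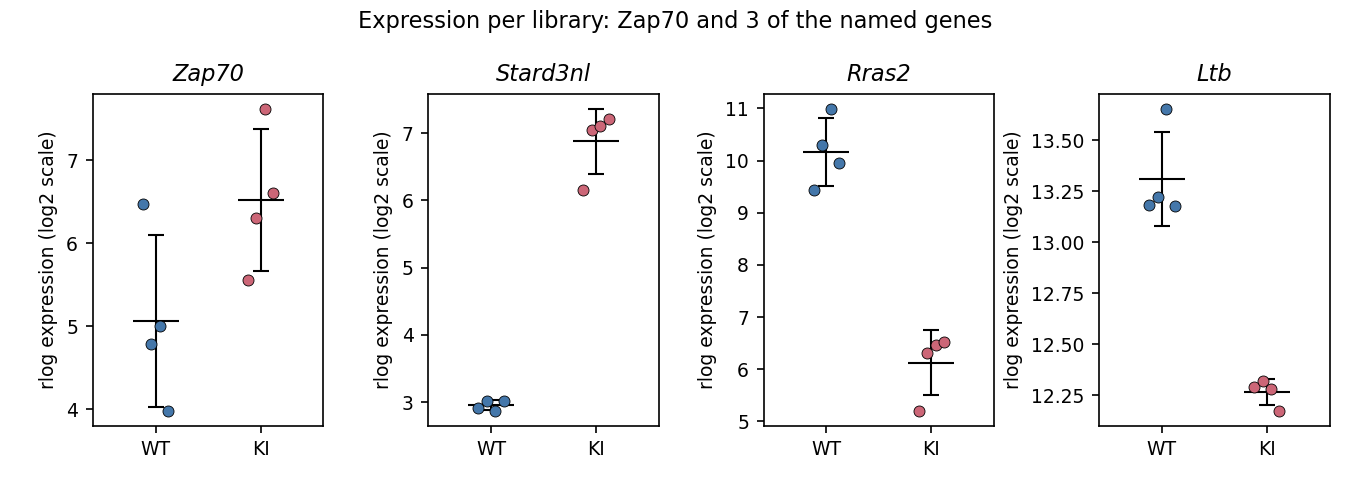
Expression of Zap70, Stard3nl, Rras2 and Ltb in each library, on the vertical axes as rlog values (log2 scale), with 1 point per library, WT in blue and KI in red; the horizontal line is the group mean and the bar its SD (n = 4). The groups overlap for Zap70, while Stard3nl lies between 6.16 and 7.21 in KI against 2.87 to 3.02 in WT, and Rras2 between 5.21 and 6.53 in KI against 9.43 or more in WT.

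Across the transcriptome, 1 gene rose and 1 gene fell in KI. Stard3nl, which encodes a late endosomal membrane protein related to the cholesterol-binding protein STARD3, rose from 2.96 ± 0.07 in WT to 6.88 ± 0.49 in KI (SD, n = 4 each). The difference was 3.92 on the log2 scale (SE 0.33), a 15.2-fold rise, with limma adjusted p = 0.0137. The WT values ran only from 2.87 to 3.02, against a median residual SD of 0.41 over the tested genes. They may be low values shrunken by the transform, so their SD need not be biological spread. The fold is a ratio on that shrunken scale, and a low level in WT cannot be told from absence. Rras2, which encodes a small GTPase of the RAS family, fell from 10.17 ± 0.66 to 6.13 ± 0.62, a log2 difference of -4.04 (SE 0.41, limma adjusted p = 0.0330). Both genes separated the groups in 4 of 4 libraries each. Stard3nl lies on chromosome 13 from 19357676 to 19395795 and Rras2 on chromosome 7 from 114046782 to 114117781, both protein-coding on the minus strand. Stard3nl overlaps the gene model Gm42683 and Rras2 overlaps Gm45615, and without a stated treatment of strand reads of the overlapping models cannot be told apart.

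The genes that ranked next did not pass the threshold, although none of them overlapped between the groups. On the higher side in KI these were Pygm, the muscle form of glycogen phosphorylase, with a log2 difference of 2.21 (SE 0.37, limma adjusted p = 0.543), Rgl1, a guanine nucleotide exchange factor for Ral, with 2.36 (SE 0.42, adjusted p = 0.577), Anxa2, a calcium-dependent phospholipid-binding protein, with 2.87 (SE 0.54, adjusted p = 0.770), and Rab31, a GTPase of vesicle traffic, with 2.02 (SE 0.39, adjusted p = 0.770). On the lower side was Ltb, which encodes lymphotoxin beta, at 12.27 ± 0.06 in KI against 13.31 ± 0.23 in WT (SD, n = 4 each, limma adjusted p = 0.197). Prr14l differed by -1.68 (adjusted p = 0.382), Wdfy2, an endosomal protein that binds phosphoinositides, by -0.67 (adjusted p = 0.543), and Pmepa1, a membrane protein induced by TGF-beta, by -2.92 (adjusted p = 0.577). At an unadjusted p of 0.05 or less there were 560 genes, 305 higher and 255 lower in KI, where 630.5 are given by chance. In 316 genes (2.51%) the groups did not overlap, where chance gives 2.86%.

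Both calls were kept without WT 1, but neither was kept with every single library left out. Stard3nl missed the threshold without WT 2 (adjusted p = 0.0848), WT 3 (0.0546), KI 2 (0.0656) or KI 4 (0.0658), and Rras2 without WT 2 (0.254), WT 3 (0.0724), WT 4 (0.0758), KI 1 (0.0568), KI 2 (0.122), KI 3 (0.0700) or KI 4 (0.0828). The log2 differences held between 3.81 and 4.16 for Stard3nl and between -4.40 and -3.74 for Rras2 over all settings tried. Pygm passed without KI 3 (log2 difference 2.57, adjusted p = 0.0490) and Prr14l without WT 4 (-1.92, adjusted p = 0.0248).

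Among the gene lists, the mitochondrially encoded genes and the oxidative phosphorylation genes were higher in KI by camera with the preset correlation. Neither list passed any of the other list tests. All 15 mitochondrially encoded genes had a positive difference, with a median of 0.71 on the log2 scale, and so did 32 of the 35 genes for nuclear-encoded subunits of oxidative phosphorylation, with a median of 0.17. Both lists passed camera with the preset correlation (adjusted p = 9.65e-07 for each), and both missed it with an adjusted p = 0.814 with an estimated correlation. Of the mitochondrially encoded genes, mt-Atp6 differed by 0.79 (SE 0.32), the ribosomal RNA gene mt-Rnr2 by 0.87 (SE 0.35) and mt-Nd2 by 0.76 (SE 0.32). The nuclear-encoded members with the smallest p were the cytochrome oxidase subunits Cox6a1, with 0.39 (SE 0.15), and Cox6c, with 0.51 (SE 0.20), and the complex I subunit Ndufa1, with 0.46 (SE 0.19). No member of either list passed over all genes tested, and 0 passed adjusted over the list alone with limma; 4 mitochondrially encoded and 5 nuclear-encoded members reached an unadjusted p of 0.05. KI 3 stood apart, with a mean of 17.17 over the mitochondrially encoded genes against 16.09 or less in the other KI libraries, all of which lay below WT 4 at 16.18. Without KI 3 the median fell to 0.36 with the preset-correlation call kept (adjusted p = 0.00330). For oxidative phosphorylation the mean of WT 4, 11.20, lay above KI 1, KI 2 and KI 3 at 11.14 to 11.18. Its median fell to 0.12 without WT 2, with the preset-correlation call kept (adjusted p = 0.00104). The exact permutation p of the list mean was 0.114 for each of the 2 lists.

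Lists of cell growth and division were also higher in KI with the preset correlation, but none with an estimated correlation; adjusted p is given below for the preset and then for the estimated correlation. Of 30 mitosis genes 29 had a positive difference (median 0.37, adjusted p = 0.0108 and 0.814), among them the kinases Ttk (0.53, SE 0.40) and Aurkb (0.51, SE 0.45) and the cyclin Ccnb1 (0.48, SE 0.47). Of 31 genes of S phase and DNA replication 26 were positive (median 0.19, adjusted p = 0.0387 and 0.814), led by the chromatin assembly subunit Chaf1b (0.71, SE 0.32) and the cyclin Ccne1 (0.62, SE 0.30). Of 27 MYC-linked genes of growth and nucleotide synthesis 24 were positive (median 0.21, adjusted p = 2.81e-04 and 0.814). In this list Gart, a purine synthesis enzyme, averaged 6.29 ± 0.94 in KI and 3.55 ± 0.63 in WT (SD, n = 4 each, limma adjusted p = 0.770 over all genes and 0.0192 adjusted over the list alone), and Bcat1, which transaminates branched-chain amino acids, differed by 2.89 (SE 0.90). Of 34 ribosome biogenesis genes 29 were positive (median 0.19, adjusted p = 0.00609 and 0.814), with Rrp12 at 0.43 (SE 0.22), and of 24 translation factors 21 (median 0.08, adjusted p = 0.0286 and 0.814), with Eif3b at 0.40 (SE 0.23). No member of these 5 lists passed over all genes tested, and Gart alone passed adjusted over the list alone. At an unadjusted p of 0.05 or less in limma there were 2 MYC-linked genes and 0 of the other 4 lists.

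WT 2 carried most of the difference in 4 of the 5 growth lists. Its mean over the mitosis genes was 6.83, against 8.57 to 9.34 in the other WT libraries, and its mean over the MYC-linked genes lay below their 10.89 to 10.95. Without WT 2 the median turned negative for mitosis (-0.16, adjusted p = 0.0671) and S phase (-0.09, adjusted p = 0.254), and it shrank to under 0.01 for the MYC-linked list (adjusted p = 0.580) and ribosome biogenesis (0.972). The translation factor median without WT 2 was 0.07 (adjusted p = 0.102), about as large as with it. With each library left out in turn the median ran from -0.16 to 0.73 for mitosis, from -0.09 to 0.36 for S phase, from 0.01 to 0.33 for the MYC-linked list, from 0.01 to 0.24 for ribosome biogenesis and from 0.05 to 0.17 for translation factors. Single libraries also ended the calls of mitosis (KI 1, 0.0642; KI 4, 0.119) and ribosome biogenesis (KI 1, 0.177). The S phase call ended without WT 4 (0.0850), KI 1 (0.101), KI 3 (0.108) or KI 4 (0.0954), and that of translation factors without WT 4 (0.0606), KI 1 (0.202) or KI 3 (0.259). With library weights the calls were lost for mitosis (median 0.23, adjusted p = 0.0811), S phase (0.07, adjusted p = 0.313), ribosome biogenesis (0.07, adjusted p = 0.239) and translation factors (0.07, adjusted p = 0.216). The S phase call was also lost without a filter on the mean, at an unmoved median of 0.19 (adjusted p = 0.0547). The translation factor call was also lost with quantile normalization (0.01, adjusted p = 0.354) and without WT 1 and KI 3 together (0.07, adjusted p = 0.268).

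**Figure D2:**
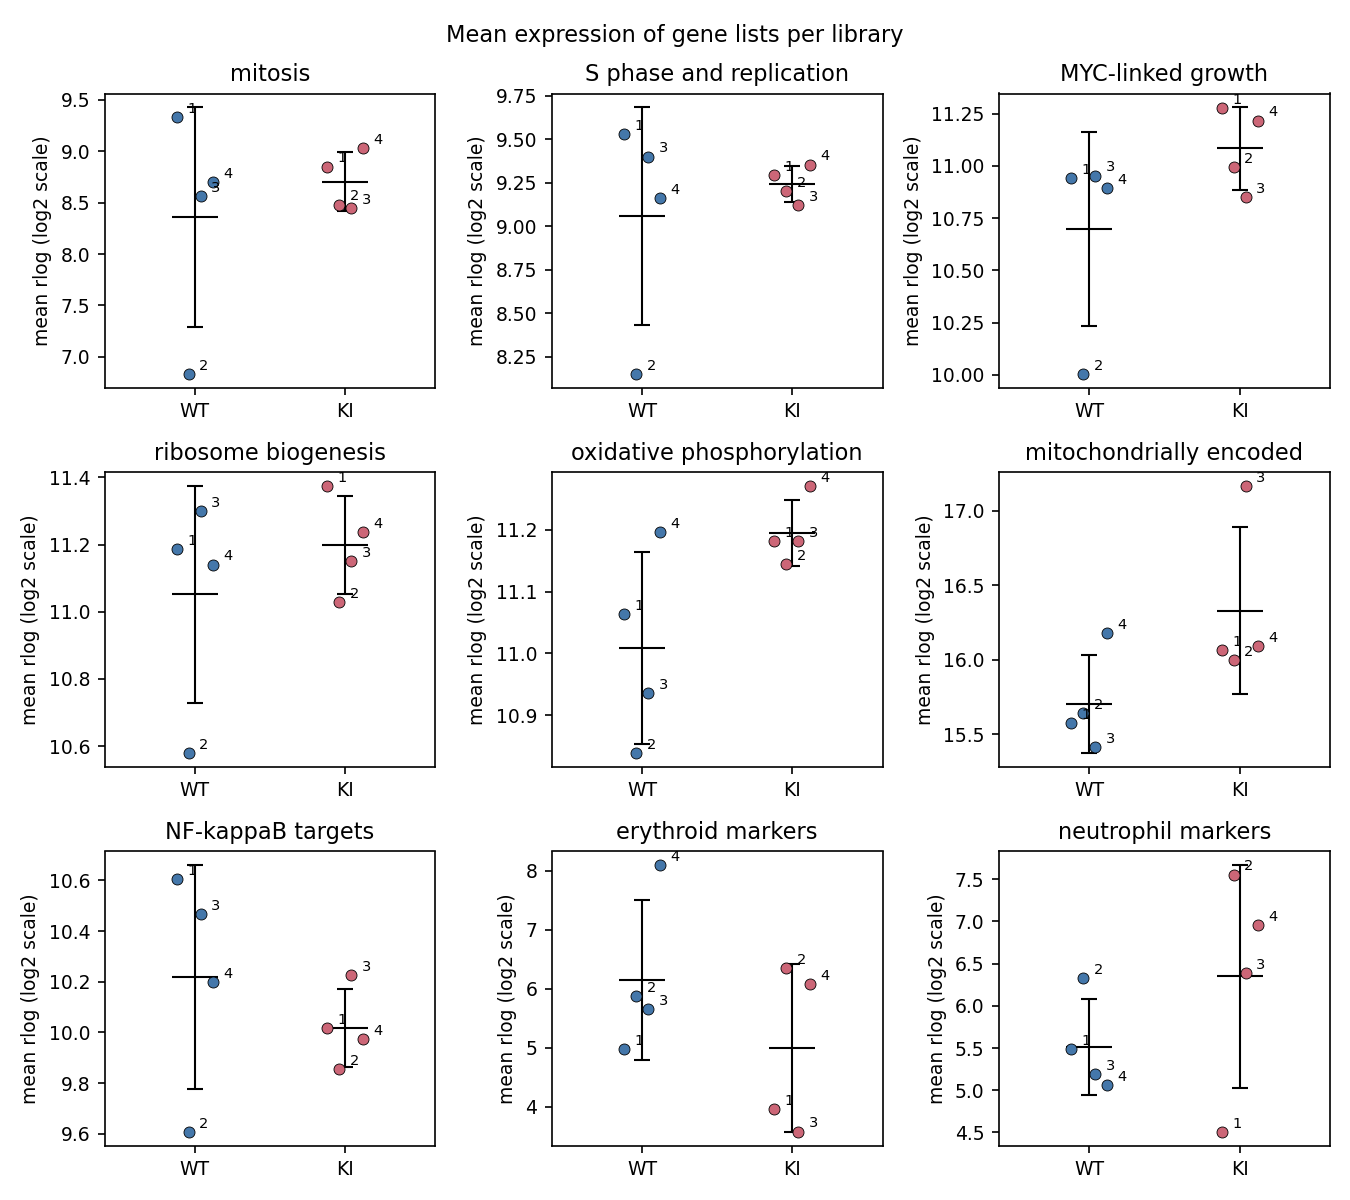
Mean expression of 9 gene lists in each library, as the mean rlog value of the tested members (log2 scale, vertical axes), with WT in blue and KI in red, the replicate number beside each point, the group mean as a line and the SD as a bar (n = 4). WT 2 lies lowest for mitosis, at 6.83, and KI 3 lies highest for the mitochondrially encoded genes, at 17.17.

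Of 23 NF-kappaB target genes 17 had a negative difference (median -0.19, camera adjusted p = 0.0213 with the preset and 0.814 with an estimated correlation), among them the subunits Relb (-0.60, SE 0.18) and Nfkb2 (-1.04, SE 0.42) and the inhibitor Nfkbia (-0.63, SE 0.33). Of 24 chemokine receptor, homing and adhesion genes 18 were positive (median 0.38, adjusted p = 0.00854 with the preset and 0.814 with an estimated correlation). The integrin chain genes Itgb2 (0.41, SE 0.16) and Itgb7 (1.48, SE 0.63) and the ectoenzyme gene Cd38 (0.36, SE 0.14) had positive differences, while that of the receptor gene Ccr7 was negative (-1.48, SE 0.65). For Ccr7 WT 1 stood at 12.73, against 9.71 to 9.98 in the other WT libraries, and the difference ran from -1.77 to -0.53 over all settings. No member of either list passed over all genes or adjusted over the list alone with limma, while 2 NF-kappaB targets and 4 homing genes (3 higher, 1 lower) reached an unadjusted p of 0.05. With 1 library left out the NF-kappaB median ran from -0.11 without WT 1 to -0.32 without WT 2, and the homing median from 0.20 without WT 1 to 0.53 without WT 4. The NF-kappaB call was lost without WT 1 (adjusted p = 0.240), WT 3 (0.139), KI 2 (0.0898) or KI 4 (0.0802) and without a filter on the mean (median -0.16, adjusted p = 0.0613), and its test turned to the other direction with the sex score as a covariate. The homing call was lost without WT 1 (0.0670) or KI 2 (0.0565) and with the level of Ighv12-3 as a covariate (median 0.25, adjusted p = 0.0948).

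Lists of B cell identity and B cell receptor signalling did not pass. The 28 B cell receptor signalling genes had a median of -0.02 (camera adjusted p = 0.527), with Rasgrp3 at -2.08 (SE 0.66) and Nfatc1 at -0.86 (SE 0.35). Within the 15 B-1 and CLL-like genes (adjusted p = 0.667), Anxa2 and the transcription factor gene Lef1 passed adjusted over the list alone, both higher in KI. Anxa2 stood at 12.43 ± 1.05 against 9.56 ± 0.75 and Lef1 at 8.59 ± 1.14 against 5.58 ± 1.46 (SD, n = 4 each, limma adjusted p over the list alone 0.00876 and 0.0350, over all genes 0.770 and 0.912). Of the 15 genes 6 were positive and 9 negative. Bhlhe40 (-2.07, SE 0.81) and Fcrl5 (-1.05, SE 0.41) were lower in KI, and neither passed adjusted over the list alone (limma adjusted p = 0.125 for each). In the chemokine and cytokine list (adjusted p = 0.248) Ltb and Il12a, a subunit of interleukin 12, passed adjusted over the list alone. Both were lower in KI, Il12a by -2.53 (SE 0.67). Neither passed over all genes (limma adjusted p = 0.197 for Ltb and 0.912 for Il12a). The chemokine and cytokine list was the 1 list called by fry's test for change in either direction (adjusted p = 0.0375). In the checkpoint list (adjusted p = 0.785) Icosl, the ligand of the costimulator ICOS, passed adjusted over the list alone. It stood at 8.65 ± 0.39 in KI against 10.23 ± 0.62 in WT and did not pass over all genes (limma adjusted p = 0.770). Adjustment over a list alone does not account for the 39 lists tested, so such passes can arise by chance. Follicular B cell (adjusted p = 0.572), germinal centre (0.539), plasma cell (0.317), T cell receptor-proximal (0.317) and immediate early genes (0.156) also did not pass. The immediate early list was called in 4 of 19 other settings with the preset correlation, and the plasma cell list in 3.

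The other lists without a call in the reported fit covered antigen presentation, stress and metabolism. Adjusted p was 0.156 for MHC class II presentation, 0.600 for MHC class I presentation, 0.951 for interferon-stimulated genes and 0.951 for the 76 cytosolic ribosomal protein genes. It was 0.995 for the BCL2 family, in which Bcl2 itself differed by -0.61 (SE 0.23), 0.527 for p53 targets, 0.342 for the unfolded protein response, 0.123 for the ATF4-linked amino acid response, 0.290 for cholesterol synthesis, 0.342 for glycolysis and 0.0693 for heat shock genes. These results varied with the setting. With the preset correlation the ribosomal protein list was called in 6 of 19 other settings, heat shock genes in 5 and MHC class II presentation in 4. KI 3 had the highest mean of the ribosomal protein genes, 14.54, against 14.22 or less in the other libraries. The direction of the test differed in sign from the list's median for the B-1, T cell receptor-proximal and checkpoint lists, and from the list's mean for the checkpoint and interferon lists.

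Markers of cells other than B cells were measured as a check on the sort. Neutrophil markers were higher in KI in all 12 tested members (median 0.92, camera adjusted p = 0.00609 with the preset and 0.814 with an estimated correlation), with Csf3r at 1.19 (SE 0.45) and Mmp8 at 1.51 (SE 0.77). Of 9 erythroid markers 8 were lower (median -1.24, adjusted p = 0.00609 and 0.814 likewise), with the globin genes Hba-a2 at -1.82 (SE 0.99) and Hbb-bs at -1.62 (SE 1.09). No member of either list passed over all genes or adjusted over the list alone with limma, while 1 neutrophil and 0 erythroid markers reached an unadjusted p of 0.05. KI 1 had the lowest mean of the neutrophil markers of all 8 libraries, at 4.50, against 5.06 to 6.33 in WT. The neutrophil median ran from 0.45 without KI 2 to 1.66 without KI 1, and the erythroid median from -0.77 without WT 4 and -0.81 without KI 3 to -1.96 without WT 1 and -2.23 without KI 2. The neutrophil call was lost without WT 4 (0.0606) or KI 2 (0.133), with a mean of at least 5 (median 0.77, adjusted p = 0.0651) and with the sex score as a covariate (median 0.72, adjusted p = 0.276). The erythroid call was lost without WT 4 (0.329), KI 1 (0.0754) or KI 3 (0.153) and with library weights (median -0.95, adjusted p = 0.0811). T cell markers (median -0.03, adjusted p = 0.539), macrophage and monocyte markers (0.38, 0.123), dendritic cell markers (0.52, 0.317) and stromal and endothelial markers (0.86, 0.156) did not pass in the reported fit. With 1 library left out, the macrophage and monocyte median ran from -0.09 without KI 3 to 0.70 without KI 1. That list was called in 4 of 19 other settings. These were without KI 1, without KI 4 (0.58), and with the sex score (0.73) or Ighv12-3 (0.74) as a covariate. The dendritic median ran from 0.19 without WT 1 to 0.75 without WT 3. The stromal median ran from 0.38 without KI 2 to 1.09 without KI 4. Both lists were called in 0 of 18 other settings. Replication-dependent histone genes, whose transcripts mostly lack a poly-A tail, were listed as a check on poly-A selection. Of these 15 genes 13 were positive (median 0.41, camera adjusted p = 0.00743 with the preset and 0.814 with an estimated correlation), with Hist1h4a at 1.01 (SE 0.44). With limma 0 passed over all genes or adjusted over the list alone, and 1 reached an unadjusted p of 0.05. The median ran from 0.20 without WT 3 to 0.86 without WT 4. The call was kept without WT 2 (median 0.43, adjusted p = 0.0120) and lost without WT 3 (0.268) or KI 1 (0.0560). It was also lost with a mean of at least 5 (median 0.41, adjusted p = 0.0907) and, at a larger median, with the sex score as a covariate (0.61, adjusted p = 0.0601). At smaller medians the call was lost with the level of Ighv12-3 as a covariate (0.28, adjusted p = 0.631) and without WT 1 and KI 3 together (0.24, adjusted p = 0.108). Too few members were tested for NK cell markers (3), platelet markers (1) and T cell receptor variable segments (0).

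In total 13 of 39 lists passed camera with the preset correlation, 10 higher and 3 lower in KI. With an estimated correlation 0 passed, the lowest adjusted p being 0.814, and 1 list, that of homing and adhesion, had an unadjusted p under the threshold (0.0355). Fry's directional test called 0 lists, and no list mean reached an exact permutation p of 0.05, the lowest being 0.0571 for the B cell receptor signalling genes.

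The leading heavy chain variable segments differed between libraries except for KI 1, KI 2 and KI 4. These 3 had the same leading pair, the heavy chain segment Ighv12-3 at 15.12, 15.90 and 14.998 and the kappa segment Igkv4-91 at 15.58, 16.87 and 15.38. KI 3 had the heavy chain segment Ighv1-55 at 14.48, with Igkv4-91, its highest kappa segment, at 8.12. WT 1 led with Ighv3-2 and Igkv1-88, WT 2 with Ighv11-2 and Igkv14-126 at 15.09 and 14.43, WT 3 with Ighv1-56 and Igkv4-80, and WT 4 with Ighv3-8 and Igkv5-43. WT 2 and WT 4 also held both members of the KI pair at high levels, Ighv12-3 at 12.52 and 12.66 and Igkv4-91 at 13.01 and 13.58. Segments with near-identical sequence can share reads, so levels of single segments are uncertain.

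As a list, 26 of the 35 tested variable segments were lower in KI (median -1.71, camera adjusted p = 0.00609 with the preset correlation and adjusted p = 0.814 with an estimated correlation), with Ighv3-2 at -4.16 (SE 1.66) and Ighv3-7 at -4.72 (SE 2.04); 0 passed over all genes or adjusted over the list alone with limma, and 2 reached an unadjusted p of 0.05. For Ighv3-2 WT 1 stood at 12.54, against 4.00 to 5.30 in the other WT libraries, and the difference ran from -5.08 to -2.23 over all settings. With 1 library left out the median of the list ran from -1.07 without WT 2 to -2.50 without WT 1. The call was lost without WT 4 (adjusted p = 0.0560) or KI 3 (0.0594) and with library weights (median -0.89, adjusted p = 0.0811). It was also lost under either other filter, with none on the mean (median -0.06, adjusted p = 0.0519) or a mean of at least 5 (-0.55, adjusted p = 0.637). Of 279 segments in the file, 35 met the filter on the mean. Igkv4-80 met it through WT 3, at 12.33 against 2.94 or less elsewhere. On the higher side, Ighv1-55 stood at 14.48 in KI 3 against 7.55 or less elsewhere. Each WT library led with a different segment and 3 KI libraries shared 1 pair, so lower values in KI may come from which segments met the filter. Constant and joining segments did not pass (adjusted p = 0.337), with Ighg3 at 1.81 (SE 0.55) and Ighj2 at -2.96 (SE 0.98).

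**Figure D3:**
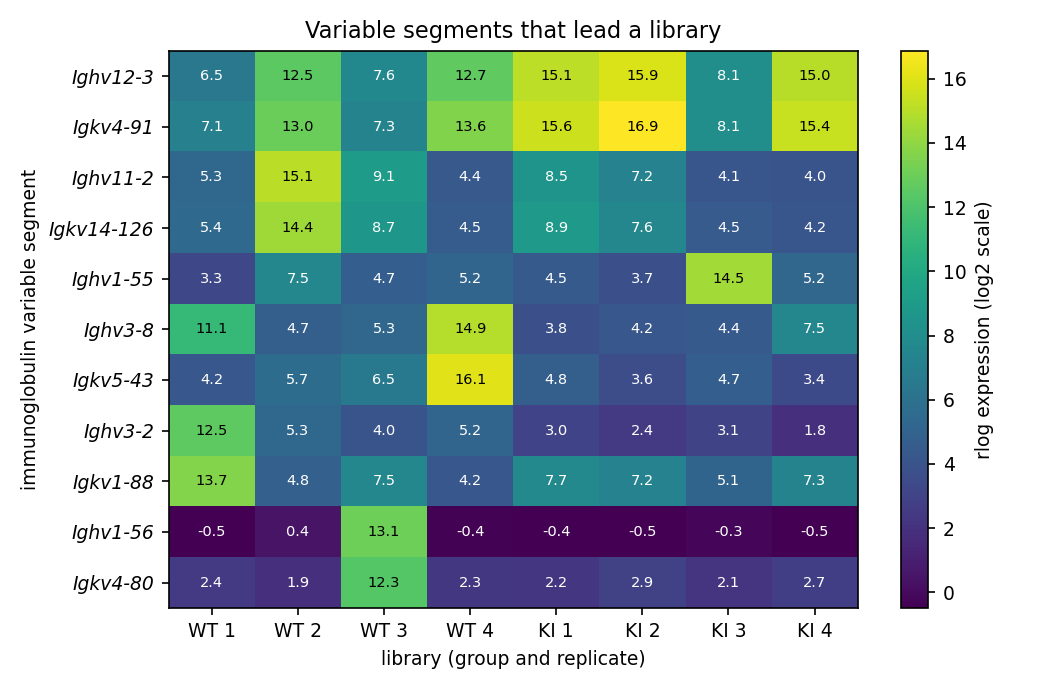
Level of 11 immunoglobulin variable segments (vertical axis) in each of the 8 libraries (horizontal axis), with colour and printed number giving the rlog value (log2 scale). Ighv12-3 and Igkv4-91 lie between 14.998 and 16.87 in KI 1, KI 2 and KI 4, and the other libraries have other leading heavy chain segments.

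The libraries did not part by group in their largest axis of variation. The first principal component held 24.0% of the variance and set WT 1 apart, at 65.5, and the second held 22.1% and set WT 2 and KI 3 apart, at 42.2 and 46.7, from the others. Pearson correlations over the tested genes averaged 0.941 within KI, 0.929 within WT and 0.933 between the groups, and no 2 libraries were near-identical, the highest correlation being 0.963. Sex as read from Xist was unbalanced between the groups, with female-type levels in 3 of 4 WT and 1 of 4 KI libraries, so it is partly confounded with genotype. Xist, the RNA that silences an X chromosome in females, stood between 10.65 and 12.58 in WT 1, WT 3, WT 4 and KI 3, and between 3.61 and 4.48 in the other libraries. The Y-linked Ddx3y stood at 10.24 in WT 2, at 7.71 in KI 2 and at 9.26 in KI 4, at 5.41 in KI 1, and at 2.16 to 2.73 in the libraries with high Xist. In KI 1 the Y-linked Kdm5d (5.32) and Uty (4.17) lay within the ranges of the high-Xist libraries, 4.92 to 5.67 and 2.24 to 4.36. The Y-linked Eif2s3y (4.38, against 1.97 to 3.41) lay above, as Ddx3y did, so the sex of KI 1 is uncertain. The sex-linked list did not pass (camera adjusted p = 0.777).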

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

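The tests of Ighv12-3, also as a covariate, of the Zap70 neighbourhood, of T cells, of the label of WT 1 and of a shared founder were chosen after the values per library had been seen. So were the use of the sex score fit to weigh Stard3nl and Rras2 and the check of why calls ended in the covariate fits, while the sex score fit itself and the counts of other splits were planned. A library is listed below when its gap to the nearest of the other 3 libraries of its group was over 0.829 of the group's range. This held in 29 of 286 groups of 4 values, where chance gives about 14.3 for normally distributed values. The genes were largely picked by small p, and the lists share genes and libraries with them. The excess over 14.3 therefore cannot be judged.

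Among single genes, KI 1 stood apart for Stard3nl (0.848 of the range, at 6.16), Rras2 (0.831, at 5.21), Il2rb (0.836) and Icosl (0.877), and KI 2 for Nme1 (0.909). KI 3 stood apart for Xist (0.883), Vcam1 (0.878), Itga2b (0.882), Nfkbia (0.856), Itgb7 (0.851), Cd200r1 (0.91) and Gins1 (0.869), and KI 4 for Ighv3-7 (0.888). WT 1 stood apart for Ccr7 (0.91), Nfkbia (0.86) and Ighv3-2 (0.849), and WT 2 for Ddx3y (0.929), Rrp12 (0.836), Ccne1 (0.837) and Cox6a1 (0.84). WT 3 stood apart for Ltb (0.904, at 13.65), and WT 4 for Pdia6 (0.83) and mt-Nd2 (0.85).

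Among list means, WT 2 was apart for the MYC-linked genes (0.938) and the sex-linked genes (0.879), WT 3 for T cell receptor-proximal genes (0.93), KI 1 for chemokine and cytokine genes (0.868), and KI 3 for glycolysis genes (0.929) and mitochondrially encoded genes (0.922).

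Chance was not excluded for either count of calls. Of the 35 splits of the 8 libraries into 4 and 4, 6, the real one included, called at least the 2 genes that the real one called, and the highest other split called 4. For the lists, 17 of the 35 splits, the real one included, called at least the 13 of the real split with the preset correlation, and the highest other split called 21.

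The first pattern weighed is the pair Stard3nl and Rras2. With the sex score as a covariate the differences were 3.89 (SE 0.38) and -4.05 (SE 0.49). With the level of Ighv12-3 they were 3.96 (SE 0.41) and -3.94 (SE 0.51), against 3.92 (SE 0.33) and -4.04 (SE 0.41) without a covariate. Both genes were chosen because they separated the groups, which neither covariate did, so sizes far from 0 could be foreseen. WT 2, with low Xist, held the WT levels of Stard3nl and Rras2 (3.02 and 10.29). KI 3, with high Xist and Ighv12-3 at 8.11, below WT 2 and WT 4, held the KI levels (7.11 and 6.46). These values argue against sex or Ighv12-3 use as the whole cause. Both calls ended in the covariate fits through precision. With the SE and degrees of freedom of both genes set back to their values without the covariate both calls returned (limma adjusted p = 0.0146 and 0.0126 for Stard3nl, 0.0327 and 0.0402 for Rras2). With only the differences set back neither did (0.138 and 0.186, 0.289 and 0.357). Sequence of another strain carried along with the Zap70 locus is argued against by the chromosomes of both genes, 13 and 7, and by the 77 tested genes within 10 Mb of Zap70, of which 3 reached an unadjusted p of 0.05 (Fisher's exact p = 1). Strain differences elsewhere in the genome, and around the knock-in if it does not lie at Zap70, were not tested and stay open. Chance stays open too, and an effect of the knock-in on both genes remains a hypothesis.

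The second pattern is the overlap of Zap70 between the groups. T cells that passed the CD5 and CD19 gate may carry Zap70 transcripts, but WT 1, the WT library within the KI range, stood 1.88 above the mean of the other WT libraries for Zap70, while over the 20 tested T cell markers the median of this difference was -0.823 (SD 1.88), lower than that of Zap70 by more than the SD; 6 were above 0, among them Cd3g (4.13), Lck (2.51) and Tcf7 (1.86), while 14 lay below, among them Cd3e, Trbc2 and Lat at 2.21, 2.88 and 1.87 in WT 1 against 6.47 for Zap70, which argues against T cells as the whole cause. Whether WT 1 holds a KI sample cannot be told apart from a correct label. Of the 5 genes called without WT 1, it lay nearer the KI mean in 3, the pseudogenes Rps3a3, Rps3a2 and Gm3508, and nearer the other WT libraries in Stard3nl and Rras2; the 3 can share reads, so they may be 1 signal, and strain, batch or read processing may underlie it. The effect of the knock-in itself on Zap70 stays open at the exact permutation p = 0.0857.

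The third pattern is the shared lead of Ighv12-3 and Igkv4-91 in 3 of 4 KI libraries and 0 of 4 WT libraries, although WT 2 and WT 4 held the pair as well, at 12.52 to 13.58. Carry-over of 1 abundant transcript spread evenly between libraries would leave like levels in the others, but Ighv12-3 spanned 6.20 on the log2 scale over the 5 libraries that did not lead with it. Use of this pair at random in either genotype cannot be told apart from a link to the knock-in, since Fisher's exact p = 0.143 is the smallest that 3 leading libraries among 4 and 4 can give, so the test could not decide. A single founder leukaemia behind the 3 libraries cannot be told apart either: Xist spanned 0.867 and was low in all 3, while Ddx3y spanned 3.85, from 5.41 in KI 1 to 9.26 in KI 4, and the second-ranked segments, which other B cells could supply, were of 2 kinds for the heavy and 3 for the kappa chain. Selection of B cells with this receptor in KI is a hypothesis that these 8 libraries do not decide.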

How the results depend on the processing

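The fits with the Ighv12-3 covariate and without WT 1 and KI 3 together were chosen after seeing the data. Against 2 genes (1 higher, 1 lower in KI) in the reported fit, 7 (4 higher, 3 lower) passed without a filter on the mean, 1 (0 higher) with a mean of at least 5, where Stard3nl was no longer tested, 1 (0 lower) without the variance trend, and 3 (2 higher) with library weights. With the sex score or Ighv12-3 as a covariate 0 passed (0 higher, 0 lower), and without WT 1 and KI 3 together 12 (10 higher, 2 lower). Both scalings, the robust fit, the threshold of 0.1, the minimum log2 change of 1 and the fit without antigen receptor segments gave 2. Leaving out 1 library gave 0 to 5 genes, 0 to 4 higher and 0 to 1 lower: 0 without WT 2, 5 without WT 1 and 4 without WT 4. Stard3nl and Rras2 were both among the genes called without WT 1, and both among the 12. They were also both among the 7, beside Ube2d2b, Gm37288, Mir1894, Gm13492 and 4930442H23Rik. In 3 fits the 1 gene called was neither of them: Rprd2 without WT 3, Wdr74 without KI 2 and Gm3608 without KI 4. Over all settings adjusted p ran from 0.00327 to 0.241 for Stard3nl and from 0.0176 to 0.424 for Rras2.

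The replicate numbers were not treated as pairs. Deviations from the group means correlated between libraries of the same number at 0.04, -0.06, -0.26 and 0.20, and 3 of the 8 libraries correlated best with their own number. With a replicate block 0 genes passed (0 higher, 0 lower), 15 lists were called, and the difference of Zap70 was again 1.46 (p = 0.250, exact, from sign changes).

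Zap70 kept its direction throughout, at 1.09 to 1.93 when 1 library was left out (exact permutation p from 0.0571 to 0.171). By limma's unadjusted p it passed in the reported fit (unadjusted p of 0.0404, difference 1.46) and also with library weights (difference 1.31) and with the sex score (1.78) or Ighv12-3 (2.31) as a covariate, where no exact test was run. Lists called numbered 13 in the reported fit, 8 to 18 when 1 library was left out, with 8 without KI 1, and 0 with an estimated correlation. The oxidative phosphorylation and mitochondrially encoded lists were called in all 19 other settings with the preset correlation.

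The test turned direction without WT 2 for S phase (median -0.086) and mitosis (-0.16), whose medians with 1 library left out reached 0.36 and 0.73 at most. It also turned for NF-kappaB targets with the sex score (-0.030) or Ighv12-3 (-0.020) as a covariate. Sex-linked genes turned with the same covariates, Ddx3y to -1.13 and -0.82 and Eif2s3y to -0.92 and -0.54. Itga2b, at 0.04 in the reported fit, turned to -0.46 with library weights, to between -0.69 and 0.36 with 1 library left out (-0.17 without WT 1, -0.12 without WT 3, -0.69 without KI 3) and to -0.90 without WT 1 and KI 3 together. The first principal component held 25.6% of the variance over all tested genes, and 25.7% to 29.0% when 1 library was left out. Except where fewer libraries or genes were used, and for Stard3nl and Rras2 in the covariate fits, the cause was not tested. Depth was unknown, so its effect on low genes was not examined.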

Other observations

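The genes and tests in this part were chosen after their values were seen. Without WT 1, the 3 genes with the smallest adjusted p were processed pseudogenes related to the ribosomal protein gene Rps3a1, on 3 different chromosomes. Rps3a3 (chromosome 13, 108670603 to 108671397) stood at 13.37 to 14.14 in KI and 13.39 in WT 1, against 6.82 to 7.26 in WT 2, WT 3 and WT 4. Rps3a2 (chromosome 14, 88123017 to 88123808) stood at 12.72 to 13.56 in KI and 12.80 in WT 1, against 5.78 to 6.74, and Gm3508 (chromosome 1, 119241962 to 119242753) at 8.10 or more in KI and 8.11 in WT 1, against 3.64 to 4.47. Rps3a1 itself (chromosome 3, 86137940 to 86142702) stood at 15.91 in WT 1, at 15.91 to 16.65 in KI and at 16.21 to 16.58 in the other WT libraries. These 4 genes can share reads, and their single levels are uncertain.

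Immunoglobulin M dominated the heavy chain constant genes in every library, with Ighm from 18.45 to 20.27. Ighd was lowest in KI 3, at 10.09, against 11.80 to 13.33 in the other 7 libraries. Jchain, which links polymeric antibodies, ranged from 8.03 in WT 1 to 15.51 in WT 4. The leading segments of WT 2, Ighv11-2 and Igkv14-126, stood at 9.07 and 8.73 in WT 3 and at 8.48 and 8.89 in KI 1.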
